A study of Macaca mulatta with 25 samples.

How the data were processed

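RNA sequencing was carried out on rhesus macaque blastocysts, the embryo stage with a fluid-filled cavity just before implantation. Per the submitters' processing notes, the tools were FastQC 0.11.8 (read quality), Trimmomatic 0.39 (adapter and quality trimming) and STAR 2.7.0 (alignment), and the genome build was Mmul_10. The authors deposited 1 table of raw read counts per gene, whole numbers with no normalization. The tool that counted reads, the annotation release, the strand setting and any removal of duplicates are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies may therefore be split or shared in ways that cannot be followed from the counts, which applies to histone, ribosomal protein and Y-linked genes above all. Per the labels' protocols, the outer coat of the embryo was taken off before freezing, and the labels do not say per library which mother, father, collection day or batch it came from, nor whether 1 library is 1 embryo.

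The table held 35395 genes in 25 libraries, and each column name matched 1 sample title. A symbol table paired 24173 of the gene identifiers with a name. Gene order was taken from the RefSeq annotation of a different build (MMU8v2.0), and was used for neighbouring genes alone, so no coordinates are given. No gene of the mitochondrial genome and no XIST entry was matched, and they were not analysed here. Library totals ran from 14219054 to 35544542 counts. In the shallowest library a CPM (counts scaled to equal library size) of 1 is 14.2 counts, so a gene near that level carries a large counting error. Lower bounds of folds and the permutation floor of the Y-linked test cover counting error alone, since reads made by PCR are not independent molecules. Within groups no library was a repeat of another: over the 84 pairs within groups the smallest chi-square per gene was 76.9, and correlations of log2 CPM ran from 0.628 to 0.926. Pairs across groups were not checked in this way.

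Genes with at least 1 CPM in at least 5 libraries were kept (13934 genes, 12605 with a symbol). Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 over all 25 libraries with the 4 groups as the only term. Comparisons were tested with edgeR's quasi-likelihood F-test with robust dispersions, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 0.9. A change always means the first-named group against the second. The interaction is the effect of the diet with testosterone less its effect without, on the log2 scale. All adjusted p-values for single genes below come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each log2 change is given with its standard error (SE). Levels are TMM-scaled CPM as mean ± SD. For a gene with no count in a group, the fold is a lower bound from 3 counts over that whole group. Over all genes tested, the median log2 change was -0.12 in both single-treatment comparisons with controls and -0.38 in embryos with both treatments. For testosterone it was -0.19 with DESeq2 size factors and 0.02 with library totals, and for the diet -0.19 and -0.01.

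Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), which compares the members with all other genes, and adjusted over the 33 lists with at least 5 tested members. Each camera call was repeated with the correlation between members estimated from the data, and with fry, which asks whether members move one way without comparing them with other genes. With an estimated correlation no list passed in any comparison. Fry called 9 lists with testosterone, 8 with the diet and 9 with both, each against controls, and 0 in the other 4 comparisons, where it gave no adjusted p under 0.05. The lists cover embryonic and extra-embryonic cell types (trophectoderm, epiblast, primitive endoderm, syncytiotrophoblast and placental hormones, oocyte transcripts), other cells that could be carried along (cumulus and granulosa cells, sperm, blood cells), Y-linked genes, energy metabolism (nuclear-encoded and mitochondrially encoded respiratory chain, glycolysis, TCA cycle, fatty acid oxidation), lipids (lipid storage and fatty acid synthesis, cholesterol synthesis and uptake), hormones (insulin and IGF signalling, androgen-responsive genes, steroid receptors and metabolism), stress (unfolded protein response, oxidative stress defence, apoptosis and p53 targets, DNA repair, hypoxia targets, autophagy and lysosome, immediate early and heat shock), and cell cycle, inflammation, interferon response, chromatin modifiers, imprinted genes, ribosomal proteins, cell junctions, Hippo signalling, embryonic genome activation and implantation. Lists, tests, comparisons and the rule for named genes were set before the data were examined.

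Genes are named by a fixed rule: in each comparison the 10 rising and the 10 falling genes with the smallest p among those that passed and have a symbol, then up to 10 further list members that passed. Where fewer than 3 passed in a direction, the 5 with the smallest p are given and said not to pass. Up to 4 members of each list are named by smallest p, and other genes named below were chosen after their values were seen. Some genes that the rule would name are not reported here, though every count and fit includes them.

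Similarity of whole transcriptomes was measured on log2 CPM with a prior count of 2. The share of squared distance between groups was tested by permuting the group labels, and the distance of libraries to their group centre by permutation over splits of both groups. Comparisons with the same controls share those libraries, so overlaps were set beside simulations of unchanged groups. The fit was tested on simulated data: counts were drawn from the real means and depths, with 200 of 13934 genes changed. In the testosterone comparison it recovered 7.5% of genes changed by a fold of 2, 41.8% by 4 and 59.1% by 8, with 3 false calls. In the diet comparison it recovered 1.5%, 29.9% and 51.5% with 4 false calls, and with both treatments 0%, 20.9% and 31.8% with 0 false calls by edgeR. With no gene changed, edgeR made 0 calls in all 3, and a planted list was found in all 3 with no other list called. These simulations and those of unchanged groups draw each gene on its own, with the same spread in all groups. They therefore do not test correlation between list members. Nor do they show how many false calls arise when a group such as C has a wider spread and outlying libraries. Random divisions of the real libraries into groups of the same sizes called a median of 9 lists for testosterone against controls, 8 for the diet against controls and 4 for testosterone against the diet.

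The alternatives were DESeq2 size factors or library totals for scaling, other filters (none, edgeR's filterByExpr, 5 CPM), DESeq2 1.42.0 in place of edgeR, limma voom with sample quality weights, which changes the test and the weight of outlying libraries at once, fits of the compared groups alone, the replicate number as a block, the number of genes detected, the Y-linked level or a surrogate variable (sva 3.50.0) as a covariate, counts thinned to the shallowest library, a prior count of 0.5, non-robust dispersions and each library left out in turn. Fits without controls 8, 11 and 12, without these and testosterone library 1, and without controls 11 and 12 were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.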

Results

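Transcripts were measured in blastocysts made in the laboratory from the eggs of female rhesus macaques under long-term treatment. From about 2.5 years of age, before puberty, 10 females per group received either control implants with standard chow (C), testosterone implants with the same chow (T), a Western-style diet rich in fat (WSD), or testosterone and this diet together (TWSD). The chow held 15% fat, 59% carbohydrate and 26% protein, and the Western-style diet 36%, 46% and 18%. After 5 to 6 years, 10 C, 7 T, 6 WSD and 3 TWSD females could undergo ovarian stimulation. Their eggs were fertilised in vitro with semen of proven males, and the embryos grew for up to 8 days. The count table held 5 C libraries (1, 2, 8, 11 and 12), 10 T libraries, 8 WSD libraries and 2 TWSD libraries (2 and 3). Total counts ran from 15272016 to 27659266 in C, 14219054 to 26753850 in T, 15005205 to 35544542 in WSD and 20381869 to 26710010 in TWSD. Between 14247 (WSD 6) and 21793 (T 11) genes were detected per library. Among C, T and WSD neither totals nor genes detected differed in exact tests over all splits (adjusted p from 0.876 to 0.98). TWSD libraries had fewer genes detected (15419 and 15543) than any control (16834 to 19640), where the 21 splits give an exact p of 0.0476 at the least (adjusted p = 0.381) and so could not pass. Embryos may share a mother or a father, so p-values measure the spread between these libraries and not between females.

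Of the squared distance between transcriptomes 19.75% lay between groups, more than with permuted labels (permutation p = 0.00733, 100000 permutations of the labels). Groups of unequal size and spread can also give a small p in this test. It therefore does not show that the libraries of each group lay close together. Left out in turn, TWSD 2 alone ended this call, at 16.92% (permutation p = 0.0934). C 8, C 11 and C 12 stood apart from the other controls, and T 1 from the other T libraries. The first principal component held 18.9% of the variance and placed C 8 at 124.5, C 11 at 169.5, C 12 at 191.7 and T 1 at 98.6. Mean correlation with the other libraries was 0.648 for C 12, 0.699 for C 11, 0.755 for TWSD 2 and 0.783 for T 1. CGA, the alpha subunit shared by chorionic gonadotropin and the pituitary gonadotropins, was at 3025 CPM in C 8, 2400 in C 11, 1073 in C 12 and 1004 in T 1, and at most 4.24 in the other 21 libraries. Without C 8, C 11 and C 12 the share between groups was 19.39% (permutation p = 0.0586). Control embryos also varied more among themselves. The mean distance to the group centre was 214.8 in C against 143 in T (exact permutation p = 0.0147 over 3003 splits) and 142.3 in WSD (exact permutation p = 0.0326 over 1287 splits), and without C 8, C 11 and C 12 these p-values were 0.5 and 0.6. The T call was lost without C 1 (permutation p = 0.0529). The WSD call was lost with a prior count of 0.5 (permutation p = 0.0622) and without any of C 1, C 12, WSD 3, WSD 4, WSD 8, WSD 9 or WSD 10.

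**Figure D1:**
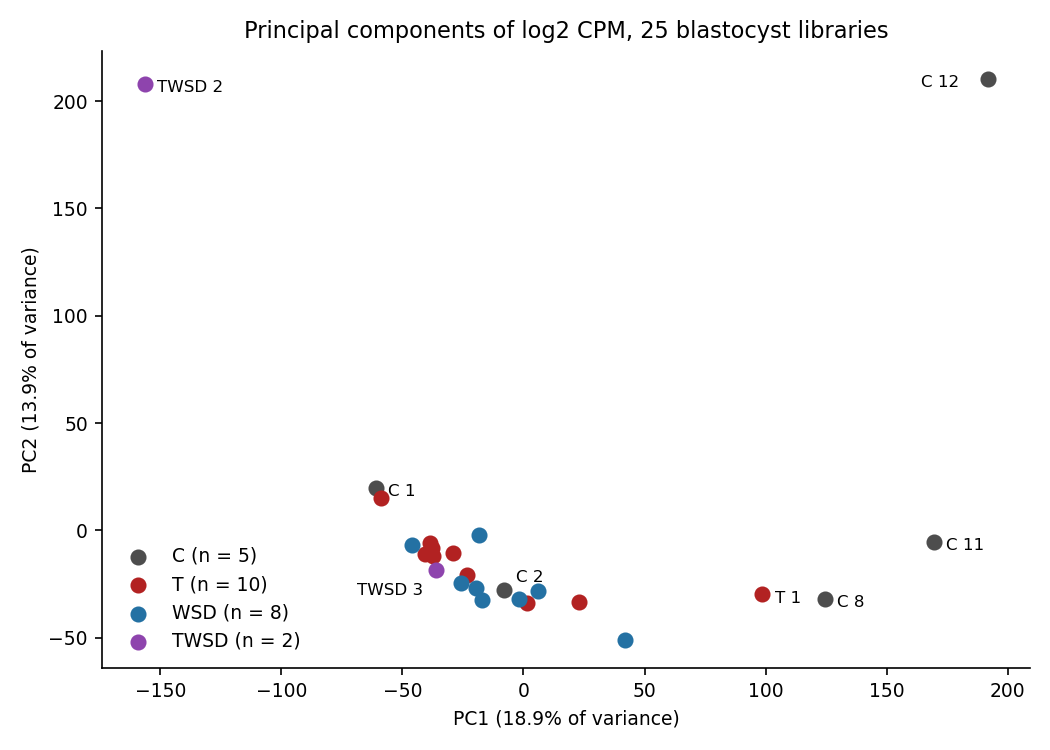
The first principal components of log2 CPM of all tested genes are drawn with 1 point per library, coloured by group; the axes give the scores and the share of variance (18.9% and 13.9%). C 8, C 11, C 12 and T 1 lie to the right at 98.6 or more on the first component, and C 12 (210.4) and TWSD 2 (207.9) lie highest on the second.

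The comparison of T with C asks what high maternal testosterone on a standard diet does to the transcripts of the embryo. Of 29 genes of the unfolded protein response, which cells switch on when proteins misfold in the endoplasmic reticulum, 9 fell and 20 did not pass. DDIT3, a transcription factor that links this stress to cell death, was at 1849 ± 3800 CPM in C (SD, n = 5) and 27.2 ± 17.9 in T (n = 10), a log2 change of -6.09 ± 0.90 (adjusted p = 0.00239). HERPUD1, which helps to degrade misfolded proteins, went from 1113 ± 1658 to 58.8 ± 30.6 CPM (-4.24 ± 0.66, adjusted p = 0.00239), and CDKN1A, the inhibitor of cyclin-dependent kinases also called p21, from 1255 ± 1704 to 57.0 ± 44.5 (-4.46 ± 0.76, adjusted p = 0.00312). POLA1 (ENSMMUG00000018433), the catalytic subunit of the DNA polymerase that starts new strands, rose 4.03-fold, from 26.5 ± 12.3 to 107 ± 35.6 CPM (log2 change 2.01 ± 0.36, adjusted p = 0.00392). CKAP5 (ENSMMUG00000003631), which lengthens spindle microtubules, rose from 87.4 ± 24.5 to 185 ± 30.6 CPM (1.08 ± 0.21, adjusted p = 0.00699).

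Of 13934 genes, 47 rose and 526 fell in T by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 1097, limma voom with quality weights 0 (1249 unadjusted) and edgeR with a surrogate variable 0 (1153 unadjusted), and without C 12 edgeR called 64. Leading genes that rose also included ANAPC1, a subunit of the complex that drives exit from mitosis (1.70 ± 0.36), the nuclear import genes KPNB1 and NUP155 (1.07 and 1.11), FABP5, which binds fatty acids (1.65 ± 0.38), the transporter SLCO1A2 (2.75), the dynein DNAH3 (2.64) and SERINC5 (1.17). Adjusted p lay between 0.0107 and 0.0231 for these. Those that fell included EIF2AK3, the endoplasmic reticulum stress kinase PERK (-3.62 ± 0.55), CAPN6 (-10.41 ± 1.59), STX5 (-2.15), CD55 (-2.94), PDLIM2 (-3.51), RSRP1 (-4.19), TRIB3 (-4.70 ± 0.79) and DNAJB9 (-2.98 ± 0.50), all with adjusted p of 0.00239 or 0.00311. Further list members that fell were SQSTM1 (-2.65), PPP1R15A (-4.05), JUNB (-2.91), KDM3A (-3.01), ZNF280A (-4.75), ATF3 (-4.38), XBP1 (-2.42), GADD45A (-2.97) and BBC3 (-2.84).

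Among the named genes, levels differed between the single controls more for those that fell than for those that rose. DDIT3 stood at 11.04 and 21.9 CPM in C 1 and C 2, inside the T range of 10.1 to 67.3, against 268 in C 8, 302 in C 11 and 8642 in C 12. POLA1 was at most 46.8 CPM in any control and at least 53.1 in any T library, and CKAP5 at most 109 against at least 123. Other risen genes were less even among controls. NUP155 was at 120.6 ± 80.5 CPM in C and FABP5 at 263 ± 172. KPNB1 was at 42.52 CPM in C 12 against 76.86 to 94.38 in the other controls. Without C 8, C 11 and C 12 the median log2 change of the 526 genes that fell went from -2.20 to -0.09. That of the 47 that rose went from 1.17 to 0.97, with 47 of 47 still higher. At these 2 controls against 10 T libraries 1 gene passed, where any other 2 controls gave 31 to 3123.

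**Figure D2:**
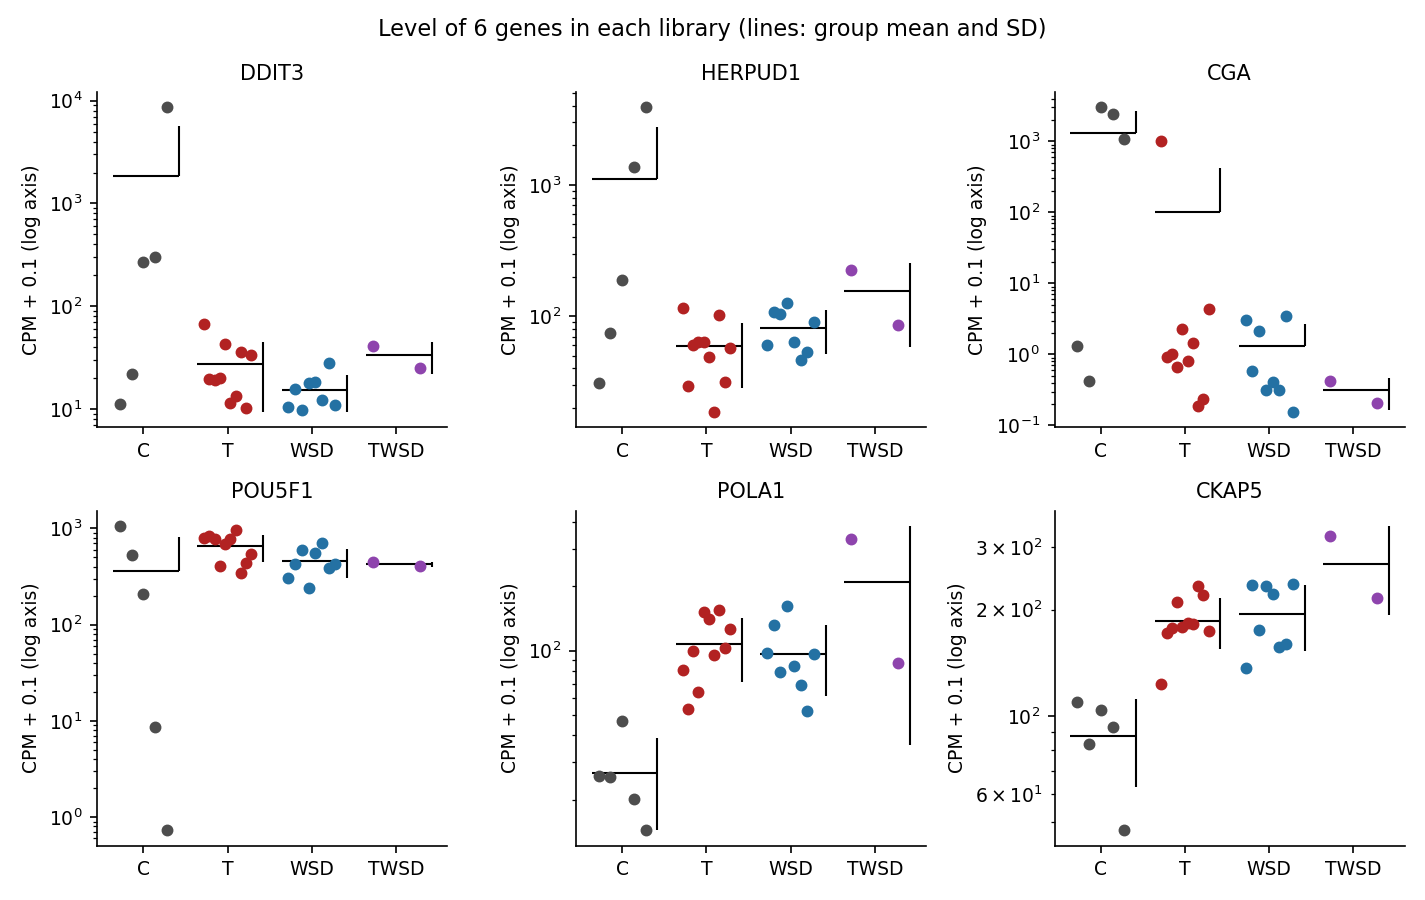
Each of the 6 panels shows 1 gene (DDIT3, HERPUD1, CGA, POU5F1, POLA1 and CKAP5), with 1 point per library by group, CPM plus 0.1 on a log axis, a line at the mean and a bar of 1 SD. Points of C 8, C 11 and C 12 lie apart from C 1 and C 2 for CGA (3025, 2400 and 1073 CPM) and DDIT3, while for POLA1 and CKAP5 all 5 controls lie below all T and WSD libraries.

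By gene list, 10 lists were higher and 6 lower in T than in C by camera with Benjamini-Hochberg adjustment over 33 lists; none of the 16 calls held with an estimated correlation. Unfolded protein response genes were lower as a list, and 15 fell when adjusted over the list alone (camera adjusted p = 1.39e-09; adjusted p = 0.236 with an estimated correlation). Without C 8, C 11 and C 12 the direction turned (camera adjusted p = 0.563). The mean log2 CPM of these genes was 9.37 in C 12, 8.13 in C 11 and 7.09 in C 8, against 6.06 to 6.93 in the other libraries. Of 38 cell cycle genes 3 rose (MCM4, CCNB1 and CENPF; log2 changes 0.72, 1.04 and 1.30), and 10 when adjusted over the list alone (camera adjusted p = 1.39e-09; adjusted p = 0.156 with an estimated correlation). Their mean was lowest in C 12 (4.99) and C 11 (5.95). Of 32 DNA repair genes BRCA1 and MSH6, which act in strand-break and mismatch repair, rose (1.11 and 1.31), with 3 adjusted over the list alone (camera adjusted p = 1.99e-07; adjusted p = 0.181 with an estimated correlation). The lowest means were again in C 12 (4.22) and C 11 (5.18). The 17 epiblast genes, markers of the cells that form the embryo proper, had no single call, also adjusted over the list alone, and were higher as a list (camera adjusted p = 6.71e-11; adjusted p = 0.156 with an estimated correlation). POU5F1 was at 1068 and 525 CPM in C 1 and C 2, 206 in C 8, 8.51 in C 11 and 0.627 in C 12.

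Of 13 genes of the syncytiotrophoblast, the fused outer layer of the placenta, ERVFRD-1, whose protein syncytin-2 fuses cells, fell (-7.68 ± 1.64, adjusted p = 0.0114), and 7 fell adjusted over the list alone (camera adjusted p = 0.00075; adjusted p = 0.257 with an estimated correlation). The list mean was 7.67 in C 8, 6.62 in C 11, 6.38 in C 12 and 6.50 in T 1. It was 1.20 to 3.97 elsewhere, and the list turned without C 8, C 11 and C 12 (camera adjusted p = 0.429). Of 30 implantation genes 3 fell, also adjusted over the list alone: HBEGF (-6.01), VEGFA (-4.01) and PTGS2 (-5.87) (camera adjusted p = 0.0157; adjusted p = 0.388 with an estimated correlation). List means were 4.80 in C 8, 4.19 in C 11 and 3.97 in C 12, against 1.06 and 2.94 in C 1 and C 2, and the list turned without the first 3 (camera adjusted p = 0.265). Of 29 apoptosis genes and p53 targets 7 fell, among them CDKN1A, GADD45A, BBC3 and MDM2, and 9 adjusted over the list alone (camera adjusted p = 0.0469; adjusted p = 0.292 with an estimated correlation). C 12 had the highest list mean (5.86). Of 28 autophagy genes 4 fell (SQSTM1, GABARAP, ULK1 and WIPI2), and 6 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.236 with an estimated correlation). C 12 was again highest (8.07). Of 5 tested cumulus and granulosa genes the matrix gene VCAN fell (-5.66), and 4 adjusted over the list alone (camera adjusted p = 0.0491; adjusted p = 0.236 with an estimated correlation). Means were 6.51 in C 8 and 8.50 in C 11 but 1.59 in C 12.

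Of the energy lists glycolysis (21 genes) passed as higher at camera adjusted p = 0.00291 (0.236 as adjusted p with an estimated correlation), with C 12 lowest (5.18, against 6.41 to 7.58 elsewhere). HK2, which commits glucose to use in the cell, rose (1.58 ± 0.42, adjusted p = 0.0329), with 2 genes adjusted over the list alone. The TCA cycle (23 genes) and the nuclear-encoded respiratory chain (56) passed as higher with no single call, adjusted over the list alone too (camera adjusted p = 0.000223 and 0.00173; adjusted p = 0.236 and 0.532 with an estimated correlation). C 12 had the lowest TCA cycle mean (5.58, against 6.94 to 7.71 elsewhere). The respiratory chain was instead lower in T without C 8, C 11 and C 12 (camera adjusted p = 0.000436). Of 27 cell junction genes CTNNA1, the catenin that ties cadherins to actin, rose (0.99 ± 0.27), alone also over the list (camera adjusted p = 0.000117; adjusted p = 0.181 with an estimated correlation). The 15 oocyte transcripts had no single call on either adjustment (camera adjusted p = 0.00399, higher; adjusted p = 0.378 with an estimated correlation). T 11 had the highest mean (5.03), C 8, C 11 and C 12 were at -0.48, -1.59 and -1.07, and the list turned without these controls (camera adjusted p = 0.813). Of 25 oxidative stress genes NQO1 fell (-3.09), with 1 rising and 3 falling adjusted over the list alone, although the list passed as higher (camera adjusted p = 0.016; adjusted p = 0.447 with an estimated correlation). C 12 had the lowest mean (3.45). Of 12 genes of embryonic genome activation ZNF280A fell, alone on either adjustment, while the list passed as higher (camera adjusted p = 0.0164; adjusted p = 0.257 with an estimated correlation).

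The comparison of WSD with C asks what the Western-style diet alone does. Embryos of the diet group also had less DDIT3, at 15.3 ± 6.02 CPM (n = 8; log2 change -6.92 ± 1.03, adjusted p = 0.00236), and less CEBPB, a transcription factor of stress and inflammation, which went from 144 ± 142 CPM in C to 8.42 ± 1.82 (-4.10 ± 0.61, adjusted p = 0.00236). ERVFRD-1 went from 1469 ± 2326 to 1.11 ± 2.04 CPM (-10.34 ± 2.01, adjusted p = 0.00762) and CYP11A1, which makes pregnenolone from cholesterol, from 959 to 181 CPM (-2.40 ± 0.53, adjusted p = 0.0134). IGF2, an imprinted growth factor, and CDKN1C, an imprinted inhibitor of cell division, fell by 8.37 and 7.54 on the log2 scale (both adjusted p = 0.0117), and turned to 0.62 and 0.42 without C 8, C 11 and C 12. Of the genes named by the rule in this comparison, 21 lost their call in that fit and 9 turned. CYP11A1 was at 2620, 806 and 834 CPM in C 8, C 11 and C 12. Among the controls DDIT3 was high in these libraries alone, as given above. POLA1 rose from 26.5 ± 12.3 to 96.4 ± 35.3 CPM (1.86 ± 0.36, adjusted p = 0.00712) and CTNNA1 from 216 ± 44.2 to 506 ± 131 (1.23 ± 0.28, adjusted p = 0.0140). Every WSD library lay above every control for POLA1 (lowest 51.9 CPM) and CKAP5 (lowest 136).

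In all, 65 genes rose and 502 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 1171, limma voom with quality weights 0 (1174 unadjusted) and edgeR with a surrogate variable 3, and without C 12 edgeR called 57. CKAP5 (1.15), NUP155 (1.24), ANAPC1 (1.55), SERINC5 (1.08), GRK6 (1.00), the clathrin heavy chain CLTC (1.08) and the protease PRSS23 (2.12) were other leading genes that rose, with adjusted p up to 0.0223. The receptor CCRL2 (-11.87), SQSTM1 (-2.99), JUNB (-3.42), ZNF280A (-5.86), RSRP1 (-4.54), CD55 (-3.08), IQCD (-3.37) and PPP1R15A (-4.51) fell with adjusted p up to 0.0047. So did the list members CDKN1A (-4.73), TRIB3 (-4.77), EIF2AK3 (-3.19), DNAJB9 (-2.92), HERPUD1 (-3.78), KDM3A (-2.92) and ATF3 (-4.41), with adjusted p up to 0.00871. Without C 8, C 11 and C 12 the median log2 change of the 502 fallen genes went from -2.39 to -0.22. That of the 65 risen genes went from 1.25 to 1.03, with 65 of 65 still higher. At these 2 controls against 8 WSD libraries 1 gene passed, where any other 2 controls gave 56 to 3119.

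Again 10 lists were higher and 6 lower with the diet, none of them with an estimated correlation. Unfolded protein response genes fell in 9 of 29 (12 adjusted over the list alone; camera adjusted p = 1.57e-07; adjusted p = 0.234 with an estimated correlation). Syncytiotrophoblast genes fell in 5 of 13, among them CGA (-10.11), the placental growth factor PGF (-4.20) and OVOL1 (-4.48), and 8 fell adjusted over the list alone (camera adjusted p = 0.000268; adjusted p = 0.234 with an estimated correlation). Apoptosis genes fell in 7 of 29, AEN among them (-2.83), and 10 adjusted over the list alone (camera adjusted p = 0.00949; adjusted p = 0.19 with an estimated correlation). Implantation genes fell in 4 of 30 (HBEGF, VEGFA, IL1RN and LIF), and 7 adjusted over the list alone (camera adjusted p = 0.0193; adjusted p = 0.468 with an estimated correlation). Autophagy genes fell in 4 of 28, and 7 adjusted over the list alone (camera adjusted p = 0.0235; adjusted p = 0.234 with an estimated correlation). CYP11A1 and VCAN of the 5 cumulus genes fell, with 3 adjusted over the list alone (camera adjusted p = 0.0145; adjusted p = 0.134 with an estimated correlation). Unfolded protein response, syncytiotrophoblast and implantation genes turned without C 8, C 11 and C 12 (camera adjusted p = 0.342, 0.781 and 0.335), and C 12 was highest for apoptosis (5.86) and autophagy (8.07).

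Cell cycle genes were higher in WSD embryos, with 4 of 38 risen (MCM4, TTK, MCM6 and CENPF; 0.75, 0.87, 1.09 and 1.40), and 10 risen and 2 fallen adjusted over the list alone (camera adjusted p = 5.2e-10; adjusted p = 0.133 with an estimated correlation). Of the DNA repair genes MSH6 rose and PMS2 fell (1.41 and -1.92), with 3 and 1 adjusted over the list alone (camera adjusted p = 3.37e-06; adjusted p = 0.19 with an estimated correlation). Cell junction genes (CTNNA1 alone, 4 over the list) passed at camera adjusted p = 5.05e-06 (adjusted p = 0.133 with an estimated correlation). Glycolysis (HK2 alone on either adjustment, 1.70 ± 0.44) passed at camera adjusted p = 0.000323 (adjusted p = 0.19 with an estimated correlation). Epiblast, TCA cycle and respiratory chain genes had no single call on either adjustment and passed as lists at camera adjusted p = 2.35e-09, 0.000268 and 0.0476 (adjusted p = 0.144, 0.234 and 0.695 with an estimated correlation). C 12 was lowest for TCA cycle (5.58) and glycolysis genes (5.18). The respiratory chain was instead lower in WSD without C 8, C 11 and C 12 (camera adjusted p = 3.16e-06). The list means of C 11 and C 12 were the lowest of all libraries for cell cycle (5.95 and 4.99), DNA repair (5.18 and 4.22), cell junction (5.56 and 4.55) and epiblast genes (0.47 and -0.25). Of 19 primitive endoderm genes, markers of the future yolk sac, the laminins LAMC1 and LAMB1 rose (1.24 and 1.10), also over the list alone. The list passed as higher (camera adjusted p = 0.0176; adjusted p = 0.486 with an estimated correlation) although its median and mean log2 change were -0.39 and -0.49. C 11 had the highest list mean (8.38) and C 12 the lowest (1.28). Of 17 trophectoderm genes TFAP2A fell (-3.65), also over the list alone, while the list passed as higher (camera adjusted p = 0.0235; adjusted p = 0.468 with an estimated correlation; lowest mean in C 1, 4.99). Of the oxidative stress genes NQO1 and PRDX5 fell (-3.48 and -0.91), on either adjustment, while the list passed as higher (camera adjusted p = 0.0445; adjusted p = 0.486 with an estimated correlation), with a median of 0.14 and a mean of -0.05. C 12 was at 3.45, and the list turned without C 8, C 11 and C 12 (camera adjusted p = 0.784).

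**Figure D3:**
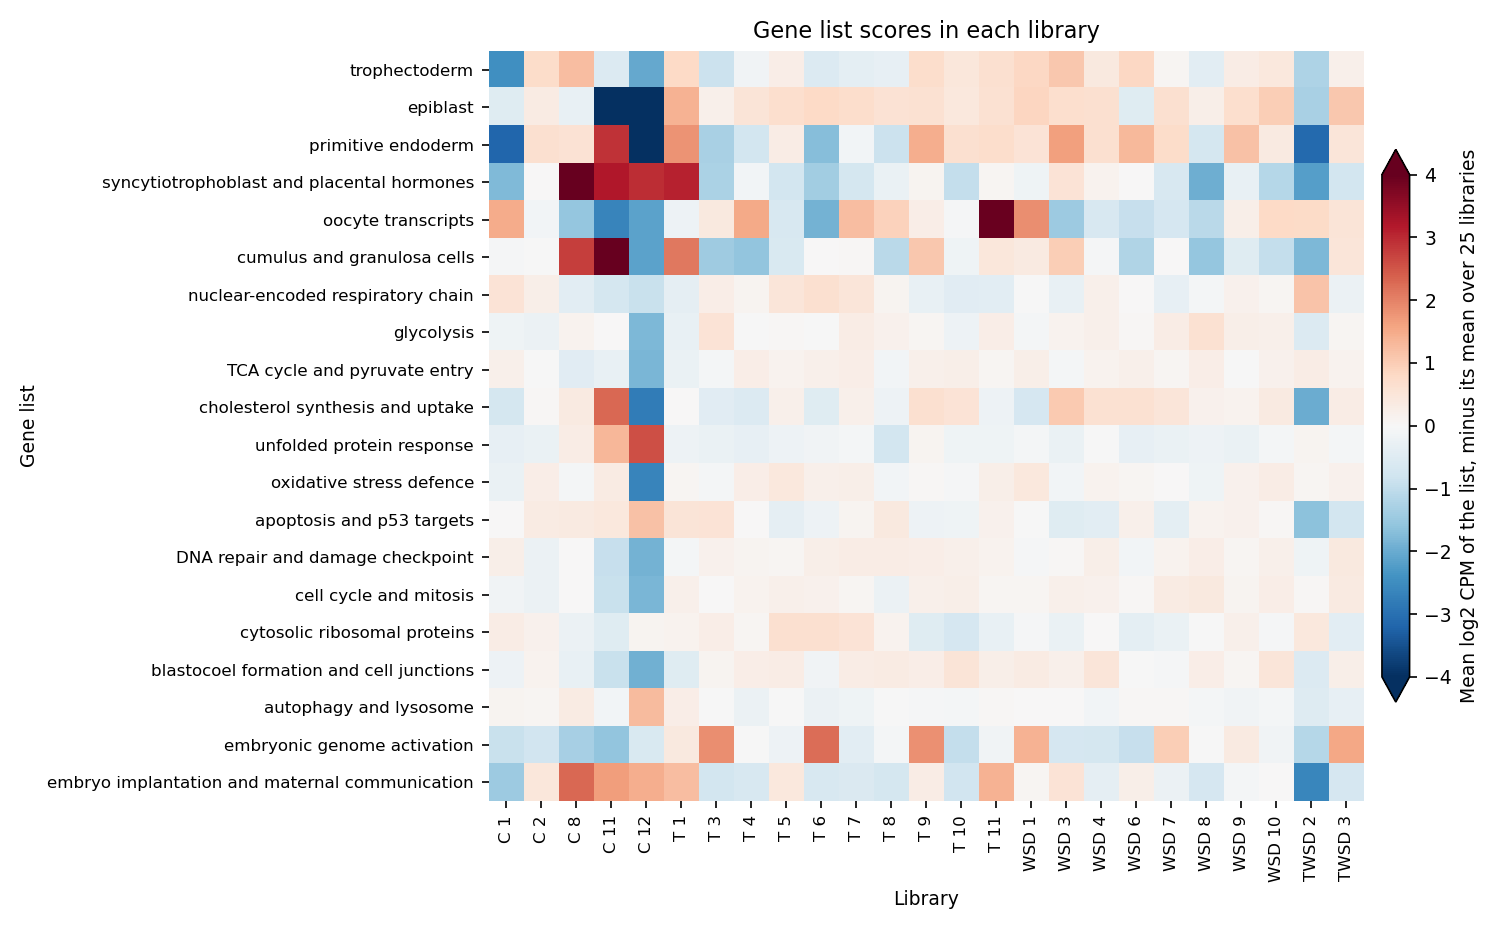
The heat map shows the 20 lists called in at least 1 comparison (lines) in the 25 libraries (columns, by group), as mean log2 CPM of the tested members less the list's mean over all libraries, with colours limited at 4 either way. C 8, C 11, C 12 and T 1 are high for syncytiotrophoblast genes (6.38 to 7.67 as mean log2 CPM), and C 11 and C 12 are low for epiblast genes (0.47 and -0.25).

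Many of the same genes were called in both comparisons with C. Of the genes called, 27 rose and 356 fell in both comparisons, where independent lists would share 0.219 and 19, and none moved in opposite directions. Log2 changes correlated across genes at r = 0.869, against a median of 0.668 (at most 0.685) in 20 simulations of unchanged groups with the same 5 controls, and their covariance was 1.457 against 0.557. Both comparisons use the same 5 controls. The simulations gave all groups the same spread of each gene. In the data the mean distance to the group centre was 214.8 in C, 143 in T and 142.3 in WSD. The simulated r and covariance may therefore be too low as a baseline. With different controls used for each treatment, at least 2 in each part (20 assignments), r had a median of 0.22 (-0.163 to 0.276), a median of 8.5 genes (0 to 44) fell in both and a median of 1 rose in both. Each treatment then has fewer controls, so r and the shared counts can also drop through added noise. With C 1 and C 2 set against T, 0 genes were called for T and 2073 for WSD.

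The direct comparison of T with WSD asks whether both single treatments act differently. No gene differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (237 at an unadjusted p under 0.05), none by limma voom with quality weights (1034 unadjusted) and 6 by DESeq2 (362 unadjusted). The smallest adjusted p was 0.446, for PHYHD1, at 1.87 ± 1.27 CPM in T (n = 10) and 13.5 ± 9.52 in WSD (n = 8), a log2 change of -2.85 ± 0.60. The next genes lower in T were GPSM1, MICAL1, CLCN2 and PDCD1, and genes with small p higher in T included LIF, CCRL2, WNT11 and GLOD4, none passing (adjusted p = 1.00). As lists, 64 of 66 cytosolic ribosomal protein genes had a positive log2 change (camera adjusted p = 1.29e-08, higher in T; adjusted p = 0.727 with an estimated correlation). Among 23 cholesterol genes 21, INSIG1 (-0.92) among them, had a negative one (camera adjusted p = 0.000108, lower; adjusted p = 0.727 with an estimated correlation). Primitive endoderm genes were lower and oocyte transcripts higher in T (camera adjusted p = 0.00978 and 0.0246; adjusted p = 0.727 with an estimated correlation for both). No member of these 4 lists passed singly, over all genes or adjusted over the list alone. T 11 held the most oocyte transcripts, with GDF9 at 99.9 and WEE2 at 192 CPM.

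The comparison of TWSD with C asks what both treatments together do, in 2 libraries. POLA1 rose from 26.5 ± 12.3 CPM (n = 5) to 210 ± 174 (n = 2; log2 change 2.99 ± 0.46, adjusted p = 0.00343), SET, a histone chaperone, from 200 ± 70.9 to 704 ± 423 (1.82 ± 0.33, adjusted p = 0.0131), MCM6, part of the replicative helicase, by 2.09 ± 0.39 on the log2 scale (adjusted p = 0.0177) and HSPA4, a heat shock protein, by 1.59 ± 0.28 (adjusted p = 0.0123). Several genes had no count in either TWSD library. MOSPD2, a protein of contacts between membranes, was at 13.3 ± 7.28 CPM in C and 0 in TWSD, at least 192-fold lower (adjusted p = 0.00108). The zinc finger gene ZNF300 was at least 167-fold lower (adjusted p = 0.0075), TCEANC at least 79.5-fold (adjusted p = 0.0104) and PLPP6 at least 225.5-fold (adjusted p = 0.0177). RELA, the p65 subunit of NF-kB, fell from 84.5 ± 83.2 to 1.67 ± 1.10 CPM (-5.67 ± 0.83, adjusted p = 0.00229) and CDKN1A from 1255 ± 1704 to 1.47 ± 1.53 (-9.70 ± 1.97, adjusted p = 0.0177).

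Of 13934 genes, 120 rose and 47 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and DESeq2's Wald test split its calls into 427 and 1568. No gene passed by limma voom with quality weights (437 unadjusted) and 4 by edgeR with a surrogate variable. CNOT8 (1.39), CKAP5 (1.62), RARS1 (1.82), SMC2 (1.78), USP10 (1.31) and CTNNA1 (1.87) were the other leading genes that rose, and TESK2 (-5.37), PAK4 (-3.44), TNFRSF10A (-7.86) and ALDH1L1 (-9.38) the other leading genes that fell. List members followed: PRKDC (1.51), MCM4 (1.16), CCNB1 (1.71), RPL7 (1.08), XRCC5 (0.98), HDAC1 (1.23), MRE11 (1.43) and PRDX2 (2.07) rose, and JUNB (-4.55) and TNFRSF10B (-6.45) fell, with adjusted p up to 0.0427. TWSD 2 carried much of the rise: POLA1 was at 334 CPM there and 87.1 in TWSD 3, and SET at 1003 and 405. With genes detected as a covariate 6 genes passed. Without TWSD 2 no gene passed by edgeR (980 unadjusted), and without TWSD 3 2784 did, where the lone library left is assumed to vary like those of the other groups.

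By list, 9 were higher and 3 lower in TWSD than in C. Of the cell cycle genes MCM6, MCM4 and CCNB1 rose, and 12 adjusted over the list alone (camera adjusted p = 7.53e-09; adjusted p = 0.213 with an estimated correlation). None of the 56 respiratory chain genes rose over all genes, and 9 adjusted over the list alone (camera adjusted p = 1.6e-08), with a list mean of 7.63 in TWSD 2 and 6.24 in TWSD 3. DNA repair genes (3 risen, 9 over the list alone) and TCA cycle genes (0 over all genes, 3 over the list alone) passed at camera adjusted p = 1.14e-06 and 9.14e-05. Implantation and syncytiotrophoblast genes were lower (no single call, 3 and 3 adjusted over the list alone; camera adjusted p = 0.0125 and 0.0212), as were apoptosis genes (CDKN1A and TNFRSF10B fell; 12 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0276). Epiblast, cell junction, oxidative stress, oocyte and glycolysis lists were higher (camera adjusted p = 0.000285, 0.0212, 0.0245, 0.0245 and 0.0411), the last with a median log2 change of 0.14 and a mean of -0.02. Of these, CTNNA1 and PRDX2 were the single calls, and adjusted over the list alone 3 cell junction genes rose and 1 fell, PRDX2 rose, and none of the other lists did. All 11 lists other than the cell cycle had an adjusted p of 0.464 with an estimated correlation. Syncytiotrophoblast means were 7.67, 6.62 and 6.38 in C 8, C 11 and C 12, 1.65 and 3.44 in C 1 and C 2, and 1.20 and 2.67 in TWSD 2 and TWSD 3. Implantation means were 4.80, 4.19 and 3.97, then 1.06 and 2.94, then -0.09 and 1.83, in the same order. Without C 8, C 11 and C 12 4 lists passed.

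The comparisons of TWSD with T and with WSD ask what the diet adds to testosterone and testosterone to the diet. Each called 7 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 that rose and 4 that fell. MOSPD2 was at 12.5 ± 5.94 CPM in T and absent from both TWSD libraries, at least 180.6-fold lower than in T (adjusted p = 0.00104) and at least 150.8-fold lower than in WSD (adjusted p = 0.00146). ZNF300 was at least 127-fold lower than in T and at least 163-fold lower than in WSD (adjusted p = 0.0157 and 0.0143), and TCEANC at least 72.8-fold and 65.7-fold (adjusted p = 0.0157 and 0.019). RELA fell by 3.87 on the log2 scale against T (24.4 ± 6.63 CPM, adjusted p = 0.0423) and by 4.16 against WSD (29.8 ± 6.21 CPM, adjusted p = 0.0203), and was at 2.45 CPM in TWSD 2 and 0.899 in TWSD 3. STAMBP, a deubiquitinating enzyme of endosomes, and CCSAP, a protein of centrioles and spindles, rose against T (1.66 ± 0.32 and 2.21 ± 0.43, adjusted p = 0.0423) and against WSD (1.87 ± 0.33 and 2.47 ± 0.44, adjusted p = 0.019 and 0.0197). SET rose against T (1.67 ± 0.29, adjusted p = 0.0157) and EXOSC8 against WSD (1.88 ± 0.36, adjusted p = 0.0416). STAMBP was at 446 CPM in TWSD 2 and 97.2 in TWSD 3, against 48.1 to 114 in T. Without TWSD 2 no gene passed by edgeR in either comparison (372 and 354 unadjusted), without TWSD 3 2469 and 2570 did and without C 12 89 and 157, and limma voom with quality weights called 0 (205 and 239 unadjusted). With library totals the 3 rises were lost in each comparison (0 rose, 4 fell), and with DESeq2 size factors 1 rose and 3 fell against T.

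**Figure D4:**
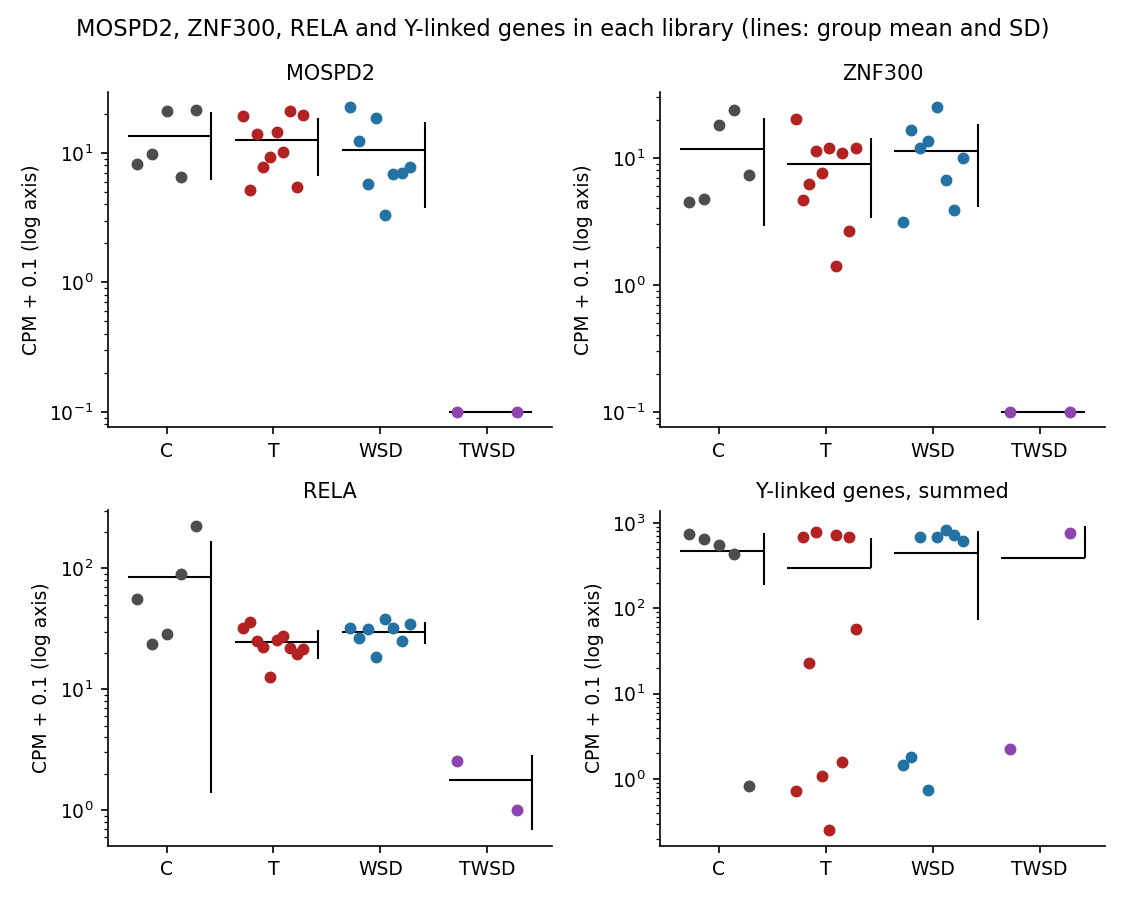
Panels for MOSPD2, ZNF300, RELA and the sum of Y-linked genes show 1 point per library by group, CPM plus 0.1 on a log axis, with a line at the mean and a bar of 1 SD. Both TWSD points lie at 0 CPM for MOSPD2 and ZNF300, and T 4 (22.7) and T 11 (57.5) lie between the high and low levels of Y-linked genes.

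The overlap of both comparisons, 2 genes risen and 4 fallen in each, shares the TWSD libraries. Independent lists would share 0.000646 and 0.00115. Log2 changes correlated at r = 0.945 across genes against 0.87 in simulations of unchanged groups, which gave all groups the same spread. Respiratory chain genes were higher in TWSD than in T and in WSD (camera adjusted p = 5.51e-06 and 1.22e-07), with NDUFB5 at 1.12 ± 0.36 and 1.17 ± 0.37, as were unfolded protein response genes (camera adjusted p = 0.00283 and 0.0196). Cell cycle genes were higher than in T alone (camera adjusted p = 0.0297). With an estimated correlation the adjusted p was 0.934 against T and 0.732 against WSD for each. The respiratory chain result came from TWSD 2 (list mean 7.63, against 6.24 in TWSD 3), and without it these genes were lower than in T (camera adjusted p = 0.0375) and not called against WSD (0.286, lower). No member passed over all genes. Adjusted over the list alone, 4 unfolded protein response genes rose against T, and 3 of these genes and 5 respiratory chain genes against WSD. HSPA5, the main chaperone of the endoplasmic reticulum, was at 12780 CPM in TWSD 2 and 2074 in TWSD 3.

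The interaction asks whether both treatments together differ from the sum of each alone. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6 genes were above and 4 below that sum. DDIT3 (7.20 ± 1.34, adjusted p = 0.034), EIF2AK3 (4.64 ± 0.89, adjusted p = 0.0371) and HERPUD1 (5.17 ± 1.04, adjusted p = 0.0486), genes low in T and in WSD against C, were no lower in TWSD than in either, at 33.0 ± 11.5 CPM for DDIT3. ZNF280A (7.12 ± 1.33), SEPTIN4 (11.95 ± 2.09) and GPBP1L1 (1.50 ± 0.29) were the others above. SEPTIN4 was at 21.45 CPM in TWSD 2 and 0.0360 in TWSD 3. Below the sum lay MOSPD2, ZNF300 and TCEANC, whose fitted values (-10.72, -10.52 and -9.49) depend on the prior count because TWSD has none. With library totals 1 gene was above and 4 below. Of 29 unfolded protein response genes 3 were above the sum, and 16 adjusted over the list alone (camera adjusted p = 1.45e-11; adjusted p = 0.476 with an estimated correlation). Respiratory chain genes were above it and epiblast, primitive endoderm and cell junction genes below, with no single call on either adjustment (camera adjusted p = 0.0392, 0.000492, 0.0392 and 0.0394; adjusted p = 0.977, 0.934, 0.977 and 0.934 with an estimated correlation). Without TWSD 2 the respiratory chain lay below the sum (camera adjusted p = 0.00177). C 12, which had 8642 CPM of DDIT3 and 196 of SEPTIN4, enters this contrast, and without it 1 gene passed. Leaving out 24 of the 25 libraries singly moved the count by over 1.5 times, to 0 without TWSD 2 (691 unadjusted) and 2235 without TWSD 3. With genes detected or the Y-linked level as a covariate 1 gene passed, and 0 by limma voom with quality weights (239 unadjusted).

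Y-linked genes, present in male embryos alone, were not called in any comparison, over all genes or adjusted over the list. Summed over the matched genes, 14 libraries had 432 CPM or more and 9 had 2.13 or less. High levels were found in 4 of 5 C, 4 of 10 T, 5 of 8 WSD and 1 of 2 TWSD libraries, with TWSD 2 low and TWSD 3 high (774 CPM). T 4 (22.7 CPM) and T 11 (57.5 CPM) lay between.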

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

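The split tests and the test of lost transcripts in the TWSD libraries were planned, and the tests of the 3 controls, the scaling, the cumulus genes, the deletion and the Y-linked genes were chosen after the results were seen. Of 282 checks for libraries far from their own group, 22 stood out, 8 of them in T 1 and 6 in C 12; about 1 in 20 would do so by chance.

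C 12 lay far from the other controls on 6 counts. The glycolysis and oxidative stress lists had means of 5.177 and 3.454 log2 CPM there, against 6.743 to 7.108 and 5.853 to 6.426 in the other controls. KPNB1 (42.52 CPM against 76.86 to 94.38) and PRDX2 (12.01 against 114.3 to 207.7) were low, and RSRP1 (4630 against 52.47 to 128.4) and BBC3 (261.4 against 16.17 to 35.24), a mediator of cell death, were high. MCM4 was low in C 11 (232.5 CPM against 409.8 to 489.9).

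T 1 had a lower mean correlation with other libraries (0.783) than the other T libraries (0.834 to 0.863), and a higher mean of the epiblast (6.491 against 5.321 to 5.9) and syncytiotrophoblast lists (6.495 against 2.018 to 3.537). IQCD (102.1 CPM against 8.736 to 23.63), ERVFRD-1 (60.36 against 0.0578 to 3.512) and CDKN1C (123.2 against 0.619 to 3.73) were high there, CKAP5 was low (122.8 against 171.7 to 232.9) and PLPP6 had 0 CPM (1.688 to 19.06 elsewhere). In single T libraries, the unfolded protein response and cell cycle lists were low in T 8 (6.061 and 6.581), PPP1R15A in T 10 (7.572 CPM against 22.53 to 48.67) and MCM6 in T 11 (244.5 CPM against 347.9 to 514.5). In WSD, DNAH3 was low in WSD 7 (1.045 CPM against 8.491 to 25.16) and RARS1 in WSD 3 (318.3 against 495.3 to 732.9), and SMC2 was high in WSD 6 (237.1 against 120.8 to 154).

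An effect of the diet that differs with and without testosterone was called for 10 genes and 5 lists. Log2 values of the 9 genes given here were 11.95 for SEPTIN4, 7.20 for DDIT3, 7.12 for ZNF280A, 4.64 for EIF2AK3, 1.50 for GPBP1L1, 5.17 for HERPUD1, -10.72 for MOSPD2, -10.52 for ZNF300 and -9.49 for TCEANC. Adjusted p by camera was 1.45e-11 for unfolded protein response, 0.000492 for epiblast, 0.0392 for both primitive endoderm and respiratory chain, and 0.0394 for cell junction genes. None of the 5 lists held with an estimated correlation, and the respiratory chain list turned without TWSD 2.

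The genes that fell against C may reflect the state of C 8, C 11 and C 12, and not the treatments. Without these libraries the median log2 change of the fallen genes was -0.09 with testosterone and -0.22 with the diet, where leaving out any other 3 controls gave -0.85 to -2.97 and -1.11 to -3.16. The scalings tried do not account for the size of these falls, as the smaller of the medians under other scalings was -1.84 and -2.11. Scaling moves all genes of a library together. The median over all genes ran from -0.19 to 0.02 with testosterone and from -0.19 to -0.01 with the diet, too little to undo such falls. The number of calls did depend on scaling and was lower with library totals, as given below. Of 16 cumulus and granulosa genes 5 were below 1 CPM in all 3 libraries, but TNFAIP6 was at 28.5, 212 and 122 CPM. FSHR, LHCGR and the abundant cumulus transcript PTX3 (0 CPM in each) were among the 5. In C 12 10 of the 16 were below 1 CPM, the matrix genes VCAN (0) and HAS2 (0.0522) among them. The others there were CYP11A1 (834 CPM), TNFAIP6 (122), STAR (88.2), FOXL2 (10.9), AMH (8.88) and AMHR2 (2.93). Attached maternal cells therefore stay open in all 3 libraries. Embryos at a later or poorer stage in the control group, or an effect of the treatments on the share of such embryos, stay open too and were not tested.

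For the genes that rose against C, the medians without C 8, C 11 and C 12 were 0.97 with testosterone and 1.03 with the diet. Leaving out any other 3 controls gave 0.86 to 1.9 and 0.92 to 2.09. These genes were chosen as risen against all controls, C 1 and C 2 included, so a positive median is largely fixed by that choice. Without C 8, C 11 and C 12 no risen gene passed in either comparison. Whether these controls contribute to the rise therefore stays open. With testosterone 1 of 100 splits, the real one, called as many genes (573, highest other 462). With the diet it was also 1 of 100 (567, highest other 419). The splits that called 462, 419 and 413 genes kept C 8, C 11 and C 12 together, which points to structure among the controls. Of the other splits drawn, only 1 with testosterone and 2 with the diet did so. A chance placing of these 3 libraries in 1 group is therefore not excluded. For lists, 6 of 100 splits called as many with testosterone (16, highest other 18), so chance is not excluded, and 4 of 100 with the diet (16, highest other 17). Between T and WSD 52 of 100 splits called as many lists (4, highest other 10), so chance is not excluded; for genes the real count was 0 (highest other 1), so 100 of 100 splits reach it by construction and the test says nothing.

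The genes without a count in either TWSD library could come from lost transcripts in low-input libraries or from a deletion. Of 300 pairs of libraries 7, the TWSD pair included, lacked as many genes that all other libraries held (2, ZNF300 and MOSPD2; highest other 6), and 5 of the 6 other pairs included C 12 or TWSD 2. MOSPD2 and TCEANC both lie on the X chromosome, and 4 of the 6 tested genes between them had 10 or more counts in both libraries, OFD1 with 3162 and 1289, against a deletion that spans both. A deletion of each gene alone, shared parents and the treatments were not tested. For the low Y-linked levels of T 4 and T 11, the mix of genes differed from each library with a high level (adjusted p = 0.00014 for each by permutation, the smallest that 100000 resamples over 14 libraries can give). This p covers counting error alone, so carry-over from another library stays open.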

How the results depend on the processing

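Fits without C 8, C 11 and C 12, without these and T 1, and without C 11 and C 12 are tests chosen after the result was seen. Settings other than a single library left out, these fits without controls included, were counted by whether they kept the number of genes called within 1.5 times. This held in 8 of 17 with testosterone, 8 of 17 with the diet and 7 of 17 with both. It held in 3 of 17 for TWSD against T, 6 of 17 for TWSD against WSD, 16 of 17 for T against WSD and 3 of 16 for the interaction. Among list results 1573 kept their status, 315 lost their call and 26 turned. Among named genes 4097 kept, 1043 lost, 2 gained and 43 turned. These totals pool all settings, and most results that kept came from leaving out 1 library. They also count as kept the genes named for T against WSD, which did not pass in the full data. With the replicate block or a surrogate variable all 30 named genes of T against C lost their call, and 29 by limma voom with quality weights. For the block, part of this is set by the design. C 12 alone holds the number 12, so the block fits it exactly and it drops out of the contrast. Leaving out C 12 by itself gave 64 calls. Other causes were not tested. In fits without TWSD 2 or TWSD 3 the lone library left is assumed to vary like the other groups.

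For T against C (573 genes), library totals called 240, DESeq2 1097, limma voom with quality weights 0 (1249 unadjusted), a fit of these groups alone 114 and a surrogate variable 0 (1153 unadjusted). Without C 8, C 11 and C 12 the count was 1, without T 1 as well 0 (693 unadjusted) and without C 11 and C 12 2. Leaving out 1 library gave 64 (C 12) to 1249 (C 1), with 1063 without C 2, 911 without T 1, 373 without T 3 and 381 without T 10. For WSD against C (567), these settings gave 321, 1171, 0 (1174 unadjusted), 30 and 3, then 1, 1 and 3. Single left-out libraries gave 57 (C 12) to 1103 (C 1), with 1073 without C 2, 377 without WSD 1, 365 without WSD 3, 363 without WSD 4, 292 without WSD 7, 345 without WSD 9 and 304 without WSD 10.

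For TWSD against C (167), library totals gave 96, no filter 92, DESeq2 1995 (427 rose, 1568 fell, against 120 and 47), limma voom with quality weights 0 (437 unadjusted), these groups alone 0 (885 unadjusted), genes detected as a covariate 6, a surrogate variable 4, and the fits without C 8, C 11 and C 12 and with T 1 also left out 18 and 32. With 1 library left out the count was 0 (TWSD 2, 980 unadjusted) to 2784 (TWSD 3), with 680 without C 1, 388 without C 2 and 335 without C 12. For TWSD against T (7), DESeq2 size factors gave 4 (1 rose, 3 fell), library totals 4 (0 rose, 4 fell), no filter 3, filterByExpr 4, DESeq2 583, limma voom with quality weights 0 (205 unadjusted), these groups alone 1, genes detected 3, a surrogate variable 3, thinned counts 4, and the fits without controls 251, 149 and 186. Removing libraries singly gave 0 (TWSD 2, 372 unadjusted) to 2469 (TWSD 3), with 89 without C 12 and 4 without each of T 3, T 4, T 5, T 7, T 8, T 9, T 11, WSD 1, WSD 3, WSD 4, WSD 7, WSD 8, WSD 9 and WSD 10.

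For TWSD against WSD (7), library totals gave 4 (0 rose, 4 fell), no filter 3, at least 5 CPM 11, DESeq2 574, limma voom with quality weights 0 (239 unadjusted), these groups alone 1, a surrogate variable 4, and the fits without controls 323, 381 and 288. Taking out 1 library gave 0 (TWSD 2, 354 unadjusted) to 2570 (TWSD 3), with 157 without C 12 and 18 without WSD 6. T against WSD (0) changed with DESeq2 alone, to 6. For the interaction (10), library totals gave 5 (1 above, 4 below), no filter 4, filterByExpr 6, at least 5 CPM 21, DESeq2 392, limma voom with quality weights 0 (239 unadjusted), genes detected 1, the Y-linked level 1, a surrogate variable 27, and the fits without controls 2, 4 and 4. Dropping 1 library gave 0 (TWSD 2, 691 unadjusted) to 2235 (TWSD 3): 98 without C 1, 123 without C 2, 18 without C 8, 25 without C 11, 1 without C 12, 36 without T 1, 4 without T 3 or T 5, 6 without T 6, 3 without T 4, T 7, T 8, T 10 or T 11, 2 without WSD 1, 5 without WSD 3 or WSD 7, 1 without WSD 4 or WSD 10, 3 without WSD 6 or WSD 9 and 4 without WSD 8.

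With the replicate block no gene passed in T against C (786 unadjusted), WSD against C (566), TWSD against C (1817), TWSD against T (876), TWSD against WSD (879) or the interaction (398). C 12 and T 5 share their numbers with no other library, so the block fits both exactly and they drop out of these contrasts. Lists numbered 7 for TWSD against C and 6 for TWSD against T with the replicate block, and the apoptosis list of T against C turned (camera adjusted p = 0.987). Correlation after removing group means had a median of -0.014 over 16 pairs of equal number (-0.376 to 0.222), 3 of them over 0.1. Over 200 other pairs the median was -0.001 (-0.336 to 0.383). This gives no sign that equal numbers mark related libraries, but so few pairs with so wide a range cannot exclude it.

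For lists, an estimated correlation gave 0 calls in every comparison, from 16, 16, 12, 3, 2, 4 and 5. Fry gave 9 for T against C, 8 for WSD against C, and 0 for TWSD against T, TWSD against WSD, T against WSD and the interaction. The fits without controls gave 7, 7 and 9 lists for T against C, 4, 4 and 6 for TWSD against C and 6, 8 and 6 for TWSD against WSD, and that without T 1 also 7 for T against WSD. Each library left out in turn gave 14 to 19, 11 to 16, 5 to 14, 2 to 5, 2 to 9, 3 to 8 and 2 to 10 lists. TWSD against C had 5 without TWSD 3, TWSD against T 5 without TWSD 2, and T against WSD 8 without WSD 6. TWSD against WSD had 5 without C 12, 9 without WSD 8, 5 without TWSD 2 and 4 without TWSD 3. The interaction had 2 without C 1, 8 without C 11, 3 without C 12, 3 without T 1, 2 without T 9, T 10, T 11 or WSD 3, 3 without WSD 6 and 10 without TWSD 2.

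The share between groups (19.75%) was 19.39% without C 8, C 11 and C 12 and 16.92% (TWSD 2) to 25.08% (TWSD 3) without 1 library. The difference in spread for T against C (-71.82) was -16.63 without C 8, C 11 and C 12, and -87.54 (C 8) to -48.24 (C 12) without 1 library, its call lost at -70.9 without C 1 (permutation p = 0.0529). That for WSD against C (-72.53) was -71.83 with a prior count of 0.5 (permutation p = 0.0622), -17.34 without C 8, C 11 and C 12, and -88.16 (C 8) to -48.87 (C 12) without 1 library, its call lost without C 1 (-71.59), C 12 (-48.87), WSD 3 (-69.96), WSD 4 (-68.57), WSD 8 (-71.26), WSD 9 (-69.64) or WSD 10 (-69.45).

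Lists that turned are given with camera adjusted p without C 8, C 11 and C 12, and then without T 1 too. With testosterone these were syncytiotrophoblast (0.429 and 0.888), oocyte (0.813 and 0.888), unfolded protein response (0.563 and 0.573), implantation (0.265 and 0.45) and respiratory chain (0.000436 and 0.00436, and 0.927 without C 11 and C 12 alone). With the diet they were syncytiotrophoblast (0.781 and 0.763), unfolded protein response (0.342 and 0.363), oxidative stress (0.784 and 0.763), implantation (0.335 and 0.302) and respiratory chain (3.16e-06 and 4.2e-06, and 0.161). Without TWSD 2 the respiratory chain list turned for TWSD against T (0.0375), TWSD against WSD (0.286) and the interaction (0.00177). Without TWSD 3 these p were 1.09e-10, 8.86e-12 and 5.89e-07, in the direction of the full data.

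Genes that turned are given with log2 changes in the same order. With testosterone these were DDIT3 (0.74 and 0.49), HERPUD1 (0.18 and 0.0199), CD55 (0.19 and 0.22), PDLIM2 (0.24 and 0.10), TRIB3 (0.20 and 0.20, and 0.0094 without C 11 and C 12 alone), SQSTM1 (0.33 and 0.12), PPP1R15A (0.35 and 0.35, and 0.0761), JUNB (0.42 and 0.33), KDM3A (0.82 and 0.75), ZNF280A (1.88 and 1.93, and 0.0472 by limma voom with quality weights) and ATF3 (0.93 and 0.77). With the diet both fits gave the same value as printed: ZNF280A 0.76, CD55 0.0448, TRIB3 0.12, EIF2AK3 0.24, HERPUD1 0.64, KDM3A 0.90, ATF3 0.89, IGF2 0.62 and CDKN1C 0.42.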

Other observations

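The gene list tests were planned, and the tests of Y-linked genes were chosen after the values were seen. Against C, Hippo pathway genes, which sort outer from inner cells, fell in 4 of 17 with testosterone, CCN2 (-3.78 ± 0.74, adjusted p = 0.00704) and CCN1, LATS2 and TEAD1 (-4.37, -2.49 and -1.92), and in 3 with the diet. Of 16 imprinted genes 3 fell with testosterone, IGF2 (-5.93), CDKN1C (-4.96) and SLC22A18 (-4.49), and 3 with the diet. Mean log2 CPM of imprinted genes was 5.91 in C 8, 5.94 in C 11, 4.97 in C 12 and 4.81 in T 1, against at most 4.39 elsewhere, and of Hippo genes 5.21, 5.03 and 6.18 in the 3 controls. Without these controls IGF2 and CDKN1C turned in the diet comparison. Of 24 lipid genes FABP5 rose and the desaturases FADS2 (-7.20) and FADS1 (-4.51) fell with testosterone, and 1 rose and 1 fell with the diet. Of 23 androgen-responsive genes SGK1, a kinase of ion transport, fell with testosterone (-1.67 ± 0.41, adjusted p = 0.0225) and SGK1 and TSC22D3 with the diet (-1.94 and -4.51). These lists did not pass as a whole (camera adjusted p = 0.0606, 0.211, 0.541 and 0.653 with testosterone, 0.182, 0.182, 0.128 and 0.616 with the diet; no list passed with an estimated correlation).

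Other lists had a few single genes and no call as a list against C, except where the report gives one (camera adjusted p with testosterone, then the diet). Inflammation genes fell in 3 of 22 with each, RELA (-1.79) and CXCL3 (-4.84) among them with testosterone (0.211 and 0.193). Insulin and IGF genes fell in 3 of 28 and 2 (0.19 and 0.309), IRS2 by 5.44 with testosterone. Hypoxia targets fell in 3 of 23 with each (0.613 and 0.741), steroid genes in 1 of 23, HSD17B2 (-5.70), and 2 (0.268 and 0.309), and interferon genes in 1 of 21, B2M (-2.57), and 0 (0.0872 and 0.473). Of 21 immediate early and heat shock genes 1 rose and 2 fell with each (0.317 and 0.223). Of 35 chromatin genes DNMT3L fell with both (-1.20 and -1.21) and TET1 rose with the diet (1.64; 0.268 and 0.125). Of 66 ribosomal genes RPL6 rose with testosterone (0.82; 0.0606 and 0.353). Of 23 cholesterol genes 1 fell with testosterone, TM7SF2, and 1 with the diet (0.874 and 0.0933). Fatty acid oxidation had none (0.143 and 0.201), nor had Y-linked genes (0.0606 and 0.482). Trophectoderm genes had 1 fall and primitive endoderm genes none with testosterone (0.159 and 0.249). Sperm and blood cell lists had 3 tested genes each and the mitochondrially encoded list 0, too few to test.

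T 4 and T 11 held 3.28% and 8.31% of the median Y-linked level of the 14 high libraries. T 11 also had the most genes detected (21793) and the highest GDF9 (99.9 CPM).

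Other pairs of comparisons shared genes too. T and TWSD, each against C, shared 16 risen and 16 fallen genes, where independent lists would share 0.405 and 1.77 (r = 0.594 against 0.377 in simulations of unchanged groups). WSD and TWSD shared 15 and 15, against 0.56 and 1.69 (r = 0.599 against 0.367). Both comparisons of each pair use the same controls, so independent lists are not a fair baseline. The simulations gave all groups the same spread, though C varied more, and may be too low a baseline too. For T and WSD, the use of different controls for each treatment, and so fewer on each side, took r from 0.869 to a median of 0.22. This was not done for the pairs with TWSD, so the shared controls may account for their overlap.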
